A study of Danio rerio with 16 samples.

How the data were processed

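Whole zebrafish (Danio rerio), labelled as larvae, were exposed for 96 h in still water to IMX-101, an explosive mixture of dinitroanisole, nitroguanidine and nitrotriazolone, per the labels' protocols. The measured concentrations are 58.2, 30.2 and 3.8 mg/L beside a control without the mixture, and the labels do not state the age of the larvae. Each of the 16 samples was the RNA of 4 pooled fish from 1 of 4 exposure replicates, labelled with Cy3 from 600 ng of total RNA with an integrity number above 7. The description of the series lists 7 concentrations between 1.9 and 121.9 mg/L, with 3.8 and 30.2 mg/L but without 58.2 mg/L. The sample labels were used as given.

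Per the file headers, the deposited scanner files hold spot intensities of 1-colour arrays of the design Agilent-036575, extracted with Agilent Feature Extraction 10.7.3.1 under the protocol GE1_107_Sep09. The processed signal in them is an intensity from which the scanner software had subtracted background and spatial trend, with no scaling between arrays, per the file headers. The deposited table of the authors holds log2 values. Set against the scanner values, it followed the log2 processed signal minus the 75th percentile of each array and the median of each probe. Up to a constant per array the differences had an SD of 0.005 to 0.007, with 99.8% or more of probes within 0.05 on each array and the largest at 0.41. These differences were taken over 32311 matched probes. Over all probes of the authors' table the column medians ran from -0.309 to 0.199. The authors' software for that step is not stated.

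Each array carried 62976 spots, of which 61657 were not controls, for 43603 distinct probes. Spots with an outlier mark were left out, the log2 processed signals of a probe's spots were averaged, and the 75th percentile of each array was subtracted. Means are printed after adding back the mean percentile, so they lie on the scale of log2 signal. A probe was tested when it was well above background on all 4 arrays of at least 1 group, which held for 32311 probes. Current symbols came from tables of accessions and synonyms, in which 32695 probes had an entry, 27815 of them by accession. For 9885 probes the current symbol differs from that on the array. The probe with the highest mean signal stood for a gene. Probe positions are those of the files, on the build danRer7. A group in which no array was well above background gives only a bound, so its fold is written as at least N-fold, computed against the lowest signal among probes well above background on each array.

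Groups were compared with limma 3.58.1 in R 4.3.3 (with version 1.17.8 of the package data.table), with a single fit of the 4 groups on all 16 arrays, 6 contrasts and, in a separate fit, a slope on the log2 of concentration plus 1. Benjamini-Hochberg adjusted p under 0.05 over all tested probes was the threshold, and ± after a log2 fold change is its standard error from that fit. For 41 gene lists, camera with its preset correlation compared each list with the other genes at 3 concentrations against control, with adjustment over the 123 tests. Camera with an estimated correlation and fry were run beside it. Fry tests whether the genes of a list move on balance in a given direction. List shifts are medians of log2 fold changes minus the median of all genes. Scores are means of a list's genes per array, relative to the control mean, and were compared with exact two-sided permutation tests over 70 splits. The list, test and naming choices were made before the data were examined.

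The genes named are, for each concentration, the 10 largest rises and 10 largest falls among genes past the threshold with all 4 treated arrays beyond all 4 controls, up to 4 changed members of each described list, and 25 sentinel genes at 58.2 mg/L, of which 23 were measured. For the trend and the contrasts between concentrations they are the 6 of smallest adjusted p. Genes with clone or accession names were passed over.

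The fit was tested on simulated data for 58.2 mg/L against control, with 50 genes changed per fold size among 32119 probes. It recovered 30% of 2-fold, 74% of 4-fold, 88% of 8-fold and 98% of 16-fold changes and called 7 of 31919 unchanged probes. The simulated trend recovered 44%, 82%, 86% and 100% at the same sizes and called 11 unchanged probes. One shifted list was called and 0 of 40 unshifted lists were. The simulated errors were independent between probes. These checks therefore do not show how many false calls of probes or lists arise where genes are correlated.

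The alternatives were normexp background correction (offset 50), quantile and cyclic loess normalization, other filters on dim probes, slide as a fixed or random block, the replicate number as a block, array weights, an intensity trend in the prior, the authors' values, other probe rules and fits, other forms of the concentration, and leaving out each array in turn. A germ cell score as a covariate and the fit without control replicate 2 and 30.2 mg/L replicate 2 were added after the data were seen. The score followed the main axis of variation among the arrays (first principal component of all genes, r = 0.972). A call lost with it therefore does not single out oocyte RNA. The arrays came from 4 slides scanned on 1 day. Slide 1 held control replicate 1, 3.8 mg/L replicate 1, 30.2 mg/L replicates 1 and 2 and 58.2 mg/L replicate 1. Slide 2 held control replicates 2 and 3, 30.2 mg/L replicates 3 and 4 and 58.2 mg/L replicate 2, slide 3 held control replicate 4 and 3.8 mg/L replicates 2, 3 and 4, and slide 4 held 58.2 mg/L replicates 3 and 4. Slide 4 held no other group, so with slide as a fixed block the contrasts of 58.2 mg/L rest on its replicates 1 and 2. Calls lost under that block can reflect the fewer arrays and do not by themselves show a slide effect. Signs within a slide were counted for probes called without the arrays of that slide, a check added after the data were seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.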

Results

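The 16 arrays measured transcripts of whole zebrafish, labelled as larvae, after 96 h in water without IMX-101 or at 1 of 3 concentrations of it. Each group had 4 arrays, with 4 pooled fish behind each. The 75th percentile of the processed signal ran from 554.4 in control replicate 2 to 2519 in 30.2 mg/L replicate 2, and 65.2% to 80.1% of probes were well above background per array, with 0 saturated. That percentile was 554.4 to 1268 in controls, below every array at 30.2 mg/L (1511 to 2519) and 58.2 mg/L (1550 to 1873). Array brightness thus went along with exposure. The number of arrays limits the precision of every value. The title of the series asks about the toxicity of IMX-101 and about oxidative stress, and each comparison with control shows which transcripts differed at that concentration.

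At 58.2 mg/L, chaperone genes and genes of heme oxygenase and a glutathione transferase rose against the controls, while a keratin gene and oocyte genes fell. The inducible chaperone gene hsp70.3 (probe on chromosome 3, 26915093 to 26915152) rose from a log2 signal of 9.25 ± 0.35 (SD, n = 4) to 14.05 ± 0.42, a 27.9-fold change (log2 4.8 ± 0.29, adjusted p = 3.9e-07). hmox1a (chromosome 3, 27021597 to 27023156), which encodes the heme-degrading enzyme heme oxygenase, rose 44.6-fold (5.48 ± 0.46, adjusted p = 8.1e-06, log2 4.08 to 5.88 over the alternatives). ptgr1.2 (chromosome 7, 25539537 to 25540345), a prostaglandin reductase gene, was well above background on 0 of 4 control arrays and was at least 22-fold higher (adjusted p = 7.3e-07), though only by log2 3.04 with normexp. krt1-19e, a keratin gene, was 103-fold lower (-6.69 ± 0.59, adjusted p = 1.2e-05).

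The other large rises were hbba2 (5.88 ± 0.78) and hbaa2 (5.20 ± 0.85), a pair of globin genes, hspa1b (5.49 ± 0.46), hsp70 (5.45 ± 0.40), ankrd1b (4.93 ± 0.61), which encodes a muscle stress protein, gsta.2 (4.25 ± 0.67), a glutathione transferase gene, and hsp70l (4.14 ± 0.33), with adjusted p from 2e-06 to 0.0011. The probes of hsp70, hsp70.3, hsp70l and hspa1b target related genes and may cross-hybridise. Their sequences were not compared, so which copy rose is uncertain. In controls hbba2 and hbaa2 had log2 signals of 7.2 and 8.8, far below the abundant hbba1 and hbaa1 (17.5 and 15.8). Their probes thus took up little signal of those copies. Cross-hybridisation with other globin genes was not tested. All 10 largest rises and krt1-19e kept their calls with slide as a block and with the germ cell score as a covariate. hspa1b was well above background on 1 of 4 controls, and its rise ran from log2 3.50 to 6.23 over the alternatives. The other large falls were mpv17 (-6.37 ± 1.16), bmp15 (-6.07 ± 1.14), an oocyte growth factor gene, imp3 (-5.80 ± 1.21), mhc2dga (-5.77 ± 1.32), foxh1 (-5.57 ± 1.12), trim35-29 (-5.52 ± 1.12), cyp11a1.1 (-5.36 ± 1.03), cth1 (-5.32 ± 1.01) and pif1 (-5.17 ± 1.12). Under the slide block, which leaves 58.2 mg/L replicates 1 and 2 for this contrast, mpv17 kept its call (-7.24, adjusted p = 0.025). The other 8 lost theirs. None of these 9 kept the call with the covariate. bmp15 is itself among the genes behind the germ cell score, so its change with the covariate (-0.78 ± 0.63) cannot test it. Of the rest, mpv17 (-4.67 ± 1.81) and mhc2dga (-4.08 ± 2.07) stayed far below 0. The others lay from -0.55 (cyp11a1.1) to 0.19 (pif1), with foxh1 at -0.37 ± 0.59.

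In all, 7247 of 32311 probes changed at 58.2 mg/L, 4329 higher and 2918 lower. They stood for 3193 and 2099 symbols, 13 of them in both directions. The median of all probes moved by 0.15, against -0.06 with normexp and -0.01 with cyclic loess. With these the split was 2849 higher to 3474 lower and 3524 higher to 3542 lower. The 4 treated arrays lay beyond the 4 controls for 5269 of 19370 genes (27.2%, against 2.86% by chance). The fit with slide as a block called 1176 (826 higher, 350 lower), 1166 of them shared with the 7247. For this contrast that fit rests on 58.2 mg/L replicates 1 and 2, so the smaller count does not show a slide effect. Of 1199 probes called without the arrays of slide 1, 97.7% had the same sign within it, against 75.5% of all probes, and of 2377 called without slide 2, 97.9% against 75%. Without control replicate 2 and 30.2 mg/L replicate 2 there were 7357 (4549 higher, 2808 lower). With the germ cell score as a covariate 828 changed (326 higher, 502 lower), 584 of them shared. Without control replicate 1 there were 4733, and without 58.2 mg/L replicate 3 there were 4774. The lower probes numbered 1925 without 58.2 mg/L replicate 1, and the higher probes 2872 without replicate 4.

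**Figure D1:**
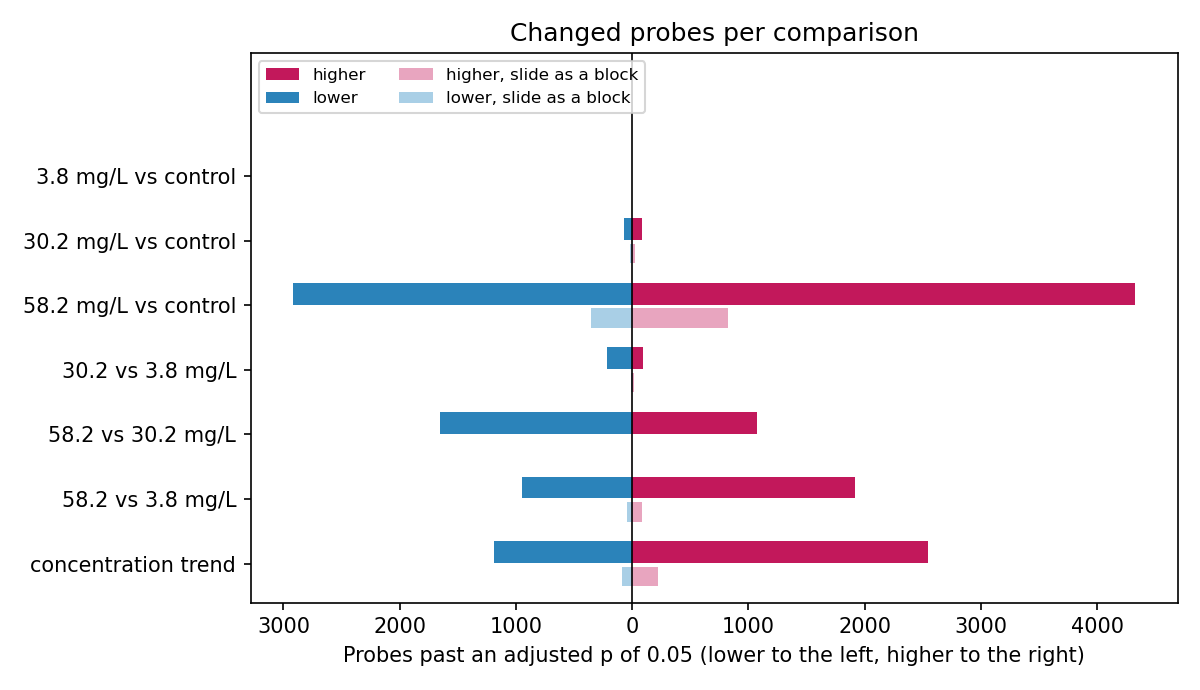
Probes past an adjusted p of 0.05 in each comparison, with lower probes to the left of 0 and higher probes to the right. Dark bars are the fit without a block and pale bars the fit with slide as a block, and the longest pair is 58.2 mg/L against control, with 4329 higher and 2918 lower.

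Chaperone and protein turnover genes rose together at 58.2 mg/L. Of 38 measured heat shock and chaperone genes, 16 rose and 0 fell (21 and 0 when adjusted over the list alone). This list shifted by 0.63 (adjusted p = 3.78e-09, and adjusted p = 0.0718 with an estimated correlation). Its small heat shock genes hspb9 and hspb9l rose by 3.60 ± 0.52 and 3.29 ± 0.32, whereas hspa5, the chaperone of the endoplasmic reticulum, had -0.67 ± 0.46 (adjusted p = 0.32). Of 47 proteasome subunits, 33 rose and 0 fell (41 and 0 when adjusted over the list alone), with psma6b and psma3 at 1.71 ± 0.35 each. Their list shifted by 0.95 (adjusted p = 5.29e-13, and adjusted p = 0.75 with an estimated correlation). Of 50 endoplasmic reticulum and integrated stress response genes, 10 rose and 2 fell (11 and 2 when adjusted over the list alone), with a shift of 0.33 (adjusted p = 0.00724, and adjusted p = 0.271 with an estimated correlation). The stress transcription factor gene atf3 rose by 2.29 ± 0.29, calr3b by 1.44 ± 0.23 and dnajb9b by 1.2 ± 0.30, and vldlr fell by 1.57 ± 0.45. These 3 lists had shifts of 0.63, 1.06 and 0.43 with slide as a block. They had 0.68 and 0.59, 1.72 and 0.62, and 0.16 and 0.45 within slides 1 and 2. Fry gave adjusted p = 2.5e-06 for heat shock, 0.00779 for the proteasome and 0.000223 for endoplasmic reticulum stress. With the germ cell score as a covariate the 3 lists kept their calls, as did hspb9l, atf3 and calr3b. psma6b (0.96 ± 0.51), psma3 (0.98 ± 0.51) and hspb9 (1.97 ± 0.65) shrank and were not called (adjusted p = 0.32, 0.32 and 0.11). dnajb9b (1.57 ± 0.47, adjusted p = 0.088) and vldlr (0.01 ± 0.50) were not called either.

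The antioxidant and glutathione list moved in both directions, with 21 of 51 members higher and 6 lower at 58.2 mg/L (25 and 8 when adjusted over the list alone). Its shift was 0.58 (adjusted p = 0.00277, and adjusted p = 0.59 with an estimated correlation), 0.54 with slide as a block, and 0.24 and 0.50 within slides 1 and 2. The thioredoxin gene txnb rose by 2.80 ± 0.27, gstp1.1 by 2.31 ± 0.40, me1 by 2.2 ± 0.28, prdx1 by 1.63 ± 0.36, gpx1a by 1.24 ± 0.28 and gclm by 0.84 ± 0.25. The superoxide dismutase gene sod1 fell by 0.76 ± 0.19, the catalase gene cat by 0.92 ± 0.28 and the metallothionein gene mt2 by 1.81 ± 0.41. Those that did not pass were srxn1 (0.69 ± 0.27, adjusted p = 0.078), sod2 (-0.29 ± 0.20, 0.33) and gstp1.2 (0.21 ± 0.24, 0.56). gclc did not pass by its brightest probe (0.69 ± 0.27, 0.079), although its other 2 probes did. Under the slide block txnb, gstp1.1 and me1 kept their calls. prdx1, gpx1a, gclm, sod1, cat and mt2 lost theirs (adjusted p = 0.084, 0.072, 0.21, 0.12, 0.13 and 0.07). With the germ cell score as a covariate txnb, gstp1.1, me1, prdx1 and gclm were called. gpx1a (0.86), sod1 (-0.80), cat (-0.51) and mt2 (-0.45) were not (adjusted p = 0.3, 0.17, 0.55 and 0.66). Of 45 aryl hydrocarbon receptor and xenobiotic enzyme genes, 11 rose and 1 fell (11 and 2 when adjusted over the list alone). This list shifted by 0.26 (adjusted p = 0.0193, and adjusted p = 0.853 with an estimated correlation), by 0.26 with slide as a block and by 0.23 and 0.26 within slides 1 and 2. Its shift was 0.08 with the germ cell score as a covariate (adjusted p = 0.681). Its member cyp1a (chromosome 18, 4985480 to 4985539), which encodes an enzyme that oxidises aromatic compounds, rose by 2.60 ± 0.30. The other risers included cyp1c2 (2.33 ± 0.32), cyp2k6 (2.28 ± 0.30) and aoc2 (1.71 ± 0.25), while cyp3a65 had -0.21 ± 0.37 (adjusted p = 0.73).

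**Figure D2:**
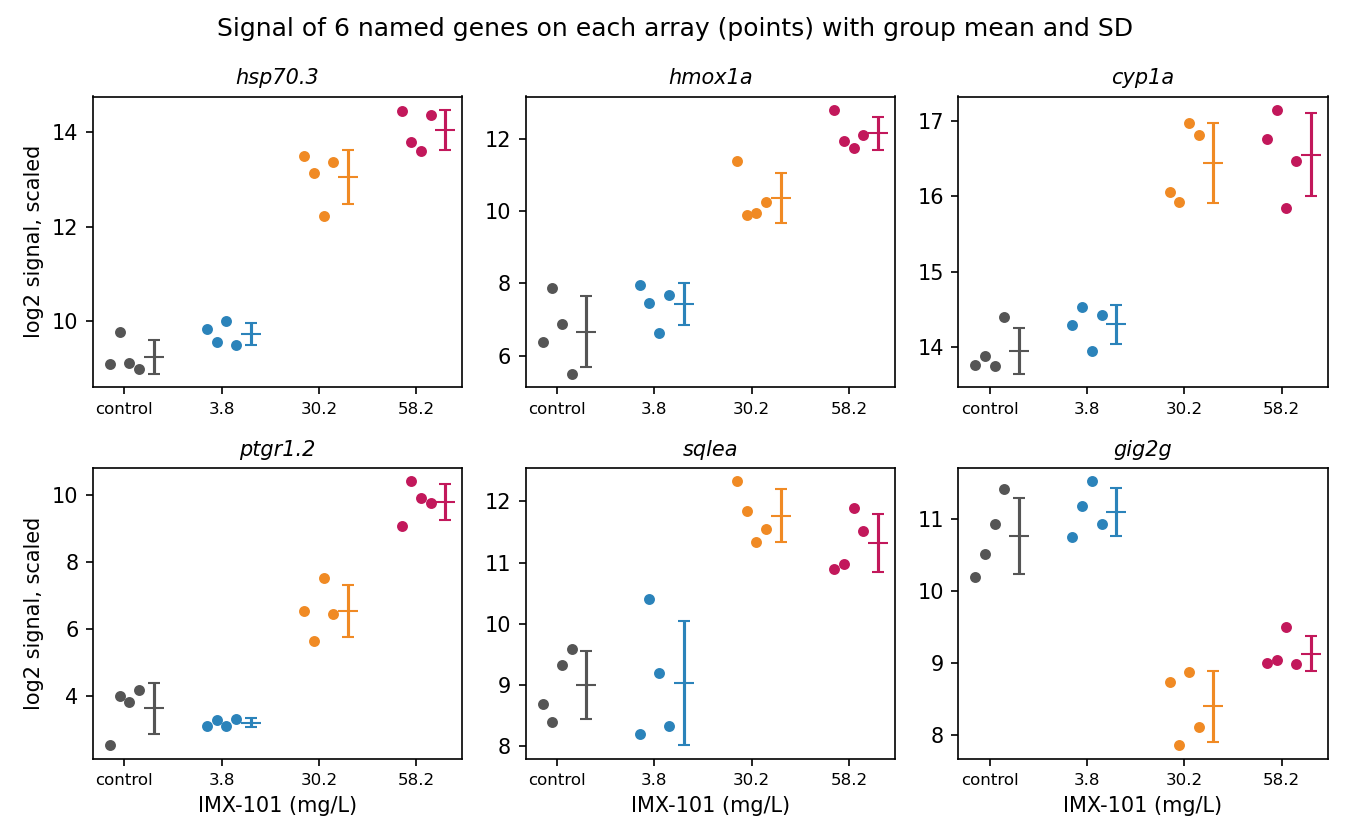
Log2 signal per array (points), with the mean and SD of 4 arrays per group, for hsp70.3, hmox1a, cyp1a, ptgr1.2, sqlea and gig2g by concentration. The mean of hsp70.3 was 9.25 in controls, 13.05 at 30.2 mg/L and 14.05 at 58.2 mg/L, and ptgr1.2 was not well above background on control arrays.

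Iron, erythroid and inflammation genes rose at 58.2 mg/L. Of 47 erythroid and heme genes, 19 rose and 1 fell (20 and 1 when adjusted over the list alone), with a shift of 0.30 (adjusted p = 0.00017, and adjusted p = 0.515 with an estimated correlation). The member that fell was hpxa (-3.73 ± 1.23), the gene of the plasma heme carrier hemopexin, and the larval globin gene hbae1.1 had -0.10 ± 0.77 (adjusted p = 0.94). Of its globin genes hbba2, hbaa2, hbae4 and hbbe3 passed and 7 did not, among them the abundant hbaa1 (0.24 ± 0.34, adjusted p = 0.65) and hbba1 (-0.04 ± 0.25, 0.93). Of 18 iron storage and transport genes, 10 rose and 0 fell both over all probes and when adjusted over the list alone, with a shift of 0.93 (adjusted p = 0.000802, and adjusted p = 0.59 with an estimated correlation). Among them were the ferritin gene fthl28 (2.33 ± 0.30) and the iron hormone gene hamp (1.62 ± 0.54). Of 37 inflammation and acute phase genes, 15 rose and 0 fell (16 and 0 when adjusted over the list alone), with a shift of 0.80 (adjusted p = 8.86e-06, and adjusted p = 0.669 with an estimated correlation). The matrix protease gene mmp13a rose by 3.59 ± 0.59, the acute phase gene saa by 3.48 ± 0.68, lect2l by 3.02 ± 0.55 and irg1l by 2.26 ± 0.67. The cytokine gene il1b had 0.93 ± 0.52 by its brightest probe (adjusted p = 0.21), and its other probe was called. The erythroid, iron and inflammation lists had shifts of 0.19, 0.87 and 0.73 with slide as a block. Within slides 1 and 2 they had 0.04 and 0.20, 0.81 and 0.58, and 0.64 and 0.83. With the germ cell score as a covariate the lists and fthl28 kept their calls. mmp13a (2.91), saa (3.05), lect2l (1.58), irg1l (1.95), hamp (0.89) and hpxa (-2.30) did not (adjusted p = 0.1, 0.15, 0.27, 0.34, 0.6 and 0.55). Under the slide block irg1l, hamp and hpxa were not called (adjusted p = 0.19, 0.13 and 0.14).

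Of 26 cholesterol biosynthesis genes, 11 rose and 1 fell at 58.2 mg/L both over all probes and when adjusted over the list alone, with a shift of 0.60 (adjusted p = 0.000922, and adjusted p = 0.75 with an estimated correlation). cyp51 rose by 2.81 ± 0.54, sqlea by 2.31 ± 0.43, acat2 by 2.00 ± 0.20 and hmgcra, the gene of the rate-limiting reductase of sterol synthesis, by 1.85 ± 0.43. Of 42 ionocyte and osmoregulation genes, 16 rose and 1 fell (19 and 1 when adjusted over the list alone), with a shift of 0.42 (adjusted p = 0.000259, and adjusted p = 0.75 with an estimated correlation). Its named members include the sodium pump gene atp1a1a.5 (2.61 ± 0.50) and the ammonia channel gene rhcga (2.2 ± 0.44). Of 13 heart markers, 8 rose and 0 fell in both counts, with a shift of 0.92 (adjusted p = 0.000671, and adjusted p = 0.75 with an estimated correlation). They included nppa (1.87 ± 0.31) and myh7 (1.65 ± 0.44). Of 43 hypoxia response genes, 8 rose and 1 fell (9 and 1 when adjusted over the list alone), with a shift of 0.15 (adjusted p = 0.0193, and adjusted p = 0.825 with an estimated correlation). Higher members included egln2 (2.25 ± 0.39) and ndrg1b (1.87 ± 0.33). The cholesterol, ionocyte, heart and hypoxia lists had shifts of 0.38, 0.41, 0.70 and 0.17 with slide as a block. Within slides 1 and 2 they had 0.35 and 0.58, 0.52 and 0.49, 0.47 and 0.89, and 0.41 and 0.16. With the germ cell score as a covariate the ionocyte, heart and hypoxia lists were not called (adjusted p = 0.0735, 0.0814 and 0.455). Their shifts were then 0.25, 0.66 and 0.02, so most of the heart shift stayed. The hypoxia list was also not called with probes above background on all arrays (0.103, adjusted p = 0.0904).

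Germ cell and cell cycle genes fell at 58.2 mg/L. Of 23 germ cell genes, 18 fell and 0 rose (19 and 0 when adjusted over the list alone), with a shift of -3.14 (adjusted p = 6.5e-12, and adjusted p = 0.59 with an estimated correlation). The oocyte genes gdf9 (-5.17 ± 1.00) and figla (-4.83 ± 0.99) fell, as did the germ cell gene nanos3 (-5.11 ± 1.2) and the egg coat gene zp2.1 (-3.39 ± 0.64). zp3, an egg coat gene of the estrogen-responsive list, fell by 2.81 ± 0.62. In controls zp3b and zp2.1 had mean log2 signals of 16.79 and 16.11, which sits badly with the label of larvae, and no label gives age or sex. Of 72 cell cycle genes, 50 fell and 0 rose (58 lower and 1 higher when adjusted over the list alone), with a shift of -2.10 (adjusted p = 9.39e-20, and adjusted p = 0.75 with an estimated correlation). Among them were the cyclin genes ccnb1 (-4.34 ± 0.90), ccnb2 (-4.25 ± 0.94) and ccna2 (-4.08 ± 0.89) and the replication licensing gene gmnn (-4.11 ± 0.79). The germ cell and cell cycle shifts were -2.47 and -1.66 with slide as a block. Within slides 1 and 2 they were -4.0 and -2.15, and -3.06 and -1.51. The germ cell score as a covariate turned the cell cycle shift to 0.47 (adjusted p = 0.000677), and left ccnb1, ccnb2 and ccna2 at -0.05, 0.20 and 0.11. These 3 were not called under the slide block either (adjusted p = 0.13, 0.17 and 0.15). Nor were gdf9, figla, nanos3, zp2.1, zp3 and gmnn (0.1, 0.13, 0.2, 0.089, 0.17 and 0.087). With the covariate zp3 and gmnn were not called (0.83 and 0.51). gdf9, figla, nanos3 and zp2.1 belong to the germ cell list, so that covariate cannot test them. The mean germ cell score was -2.94 ± 1.03 (SD, n = 4) at 58.2 mg/L against 0 ± 0.67 in controls (exact permutation p = 0.0286, the smallest 4 against 4 can give, and 0.0858 adjusted over 12 tests). It was lower on 4 of 4 arrays than on any control. Across the 16 arrays the germ cell and cell cycle scores correlated (Pearson r = 0.974, Spearman rho = 0.965), with r = 0.972 without the 2 arrays farthest from the median germ cell score and r = 0.969 for deviations from slide means. The permutation p of the first 3 was 1e-05, the smallest the permutations can give, and that within slides was 7e-05 (adjusted p = 1.2e-05 and 7e-05 over 5 relations).

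**Figure D3:**
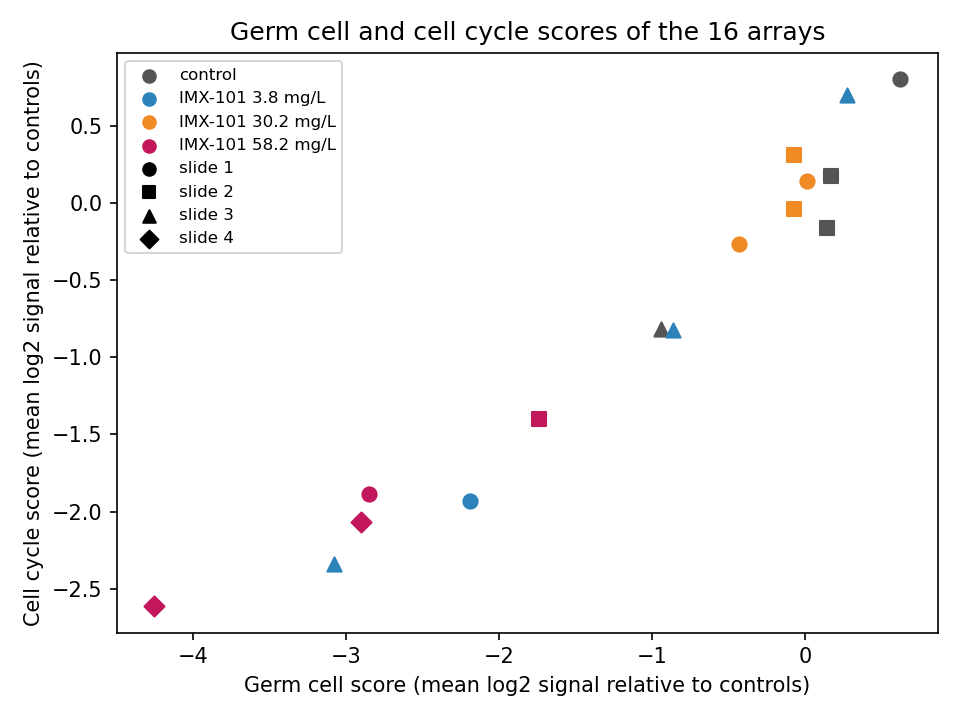
Germ cell and cell cycle scores per array, as mean log2 signal of the list's genes relative to the control mean, in the 4 groups. The germ cell score ran from -4.26 to -1.74 at 58.2 mg/L, from -0.94 to 0.62 in controls and from -3.08 to 0.28 at 3.8 mg/L.

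Surface and gut genes fell as well. Of 40 skin and keratin genes, 9 fell and 2 rose (12 and 2 when adjusted over the list alone), with a shift of -0.75 (adjusted p = 0.00145, and adjusted p = 0.853 with an estimated correlation). Lower members included anxa1b (-1.55 ± 0.34), icn (-1.50 ± 0.33) and cyt1 (-1.44 ± 0.31), while the claudin gene cldnf rose by 1.36 ± 0.39. Of 29 intestine markers, 9 fell and 0 rose in both counts, with a shift of -0.39 (adjusted p = 0.0119, and adjusted p = 0.853 with an estimated correlation). They included the chitinase gene chia.3 (-4.01 ± 0.70), apoa4a (-2.58 ± 0.61) and the bile acid binding gene fabp6 (-1.65 ± 0.39). The intestine list was not called with normexp (adjusted p = 0.0564). The skin and intestine shifts were -0.76 and -0.58 with slide as a block. Within slides 1 and 2 they were -1.09 and -0.47, and -0.55 and -0.65. The other 22 lists at 58.2 mg/L were not called, with adjusted p from 0.0748 to 0.972.

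The calls of the remaining lists at 58.2 mg/L depended on the scaling, on other settings or on single arrays. Of 79 cytosolic ribosomal proteins, 2 fell, rps26 (-0.74 ± 0.25) and rpl37 (-0.70 ± 0.23, with another probe called at 0.76), and 0 passed when adjusted over the list alone. That list shifted by -0.50 (adjusted p = 8.79e-08, and adjusted p = 0.853 with an estimated correlation) and by -0.48 with slide as a block, and within slides 1 and 2 it had -0.54 and -0.37. Its shift was 0.01 with quantile normalization (adjusted p = 0.388) and -0.08 with cyclic loess (0.0617). Of 24 members of the interferon response list, 2 fell in both counts, irf1a (-1.81 ± 0.31) and xaf1 (-1.46 ± 0.36). That list had a shift of -0.44 (adjusted p = 0.0358, and adjusted p = 0.853 with an estimated correlation), -0.52 with slide as a block, and -0.24 and -0.73 within slides 1 and 2. It lost its call without 58.2 mg/L replicate 2 (adjusted p = 0.0786) or 3 (0.0644), without control replicate 2 (0.128) or 4 (0.0525), with normexp (0.0697), with the germ cell score as a covariate (0.0771), with array weights (0.103), with slide as a random block (0.0529), with probes above background on all arrays (0.073) and without control replicate 2 and 30.2 mg/L replicate 2 (0.12). With the authors' values its shift was -0.26 and was not called (0.0706). In the other settings named, leaving out single arrays aside, its shift stayed between -0.384 and -0.645, so the call was lost but not the shift. Of 58 skeletal muscle contractile genes, 5 rose and 6 fell (5 and 3 when adjusted over the list alone). Their shift was -0.49 (adjusted p = 0.0453, and adjusted p = 0.987 with an estimated correlation), -0.52 with slide as a block, and -0.67 and -0.24 within slides 1 and 2. It lost its call with normexp (0.366), cyclic loess (0.716), quantile normalization (0.882), slide as a random block (0.163), the mean of a gene's probes (0.324) and probes above background on all arrays (0.0505), and without 58.2 mg/L replicate 1 (0.154) or 2 (0.0812) or control replicate 4 (0.447). Of the 111 named genes called at 58.2 mg/L, 95 kept the call without any 1 of the 8 arrays, and cat, cd8a, cldnf, fabp10a, gclm, hamp, hpxa, irg1l, opa1, pgam2, prkn, rpl37, rps26, tfam, ucp3 and vldlr did not. Leaving out 58.2 mg/L replicates 1 to 4 ended 14, 9, 10 and 7 of these calls, and leaving out control replicates 1 to 4 ended 9, 4, 11 and 8. Under the slide block 58 of the 111 were called, and 34 with the germ cell score as a covariate. Among those lost with the covariate, bmp15, gdf9, figla, nanos3 and zp2.1 belong to the germ cell list itself, so their loss was built in.

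At 30.2 mg/L chaperone, heme oxygenase and sterol synthesis genes rose, as did cyp1a. hsp70 rose 21.9-fold (log2 4.45 ± 0.40, adjusted p = 7.2e-05), from a log2 signal of 7.51 ± 0.76 (SD, n = 4) to 11.96 ± 0.62, and hsp70.3 rose 14-fold (3.81 ± 0.29, adjusted p = 1.2e-05). hmox1a rose 13-fold (3.70 ± 0.46, adjusted p = 0.0013, log2 2.29 to 4.26 over the alternatives) and cyp1a 5.66-fold (2.5 ± 0.30, adjusted p = 0.0013). The sterol synthesis genes cyp51 and sqlea rose 8.34-fold (3.06 ± 0.54, adjusted p = 0.021) and 6.77-fold (2.76 ± 0.43, adjusted p = 0.01). The largest fall was that of lgals9l4, a galectin gene, which was well above background on 0 of 4 treated arrays and at least 4.68-fold lower (adjusted p = 0.028), but -1.70 with normexp and not called (0.076).

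The other large rises at 30.2 mg/L were hsp70l (3.33 ± 0.33), slc45a3 (3.31 ± 0.55), ptgr1.2, which was at least 2.32-fold higher but had log2 0.60 with normexp and was not called (adjusted p = 0.29), and twf2b (2.51 ± 0.45). slc45a3 was well above background on 2 of 4 controls, and its rise ran from log2 1.43 to 3.72 over the alternatives. The other large falls were mfap4.4 (-2.98 ± 0.56), tgm2a (-2.53 ± 0.44), gig2g (-2.38 ± 0.29), tgm5l (-2.29 ± 0.47), abcg2b (-2.15 ± 0.35), tm4sf5 (-1.74 ± 0.33), gc (-1.71 ± 0.34), which encodes the vitamin D binding protein, pklr (-1.70 ± 0.27), the gene of liver pyruvate kinase, and trim101 (-1.46 ± 0.31). Their adjusted p ran from 0.00016 to 0.048. In all, 152 probes changed, 86 higher and 66 lower, for 70 and 60 symbols, and with normexp the split was 58 higher to 108 lower. The fit with slide as a block called 38 (23 higher, 15 lower). Without the arrays of slides 1 and 2 in turn only 6 and 16 probes were called, of which 5 and 14 had the same sign within the slide left out. Without control replicate 2 and 30.2 mg/L replicate 2 there were 177 (90 higher, 87 lower), 79 of them shared with the 152, and 656 (295 higher, 361 lower) with the germ cell score as a covariate. Leaving out 30.2 mg/L replicates 1, 2 and 4 gave 44, 69 and 41 changed probes, and leaving out control replicates 1, 2 and 3 gave 101, 278 and 70. Without control replicate 4 there were 96 higher and 30 lower. The majority was lower without 30.2 mg/L replicate 3 (60 higher, 71 lower) or control replicate 1 (49 and 52), with array weights (1613 and 1907) and in a fit of only these 2 groups (26 and 31). The groups separated completely for 6.82% of genes, against 2.86% by chance. Of the 25 named genes, hsp70, hsp70.3, hsp70l, hmox1a, ptgr1.2, sqlea, cyp1a, gig2g and pklr kept their calls without any 1 of the 8 arrays. The others lost theirs without at least 1 array. Leaving out 30.2 mg/L replicates 1 to 4 ended 16, 11, 4 and 15 of the 25 calls, and leaving out control replicates 1 to 4 ended 11, 3, 10 and 8. Under the slide block 9 of the 25 were called, the same genes with hmgcra (adjusted p = 0.027) in place of pklr (0.054).

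Of 26 cholesterol biosynthesis genes, 6 rose and 0 fell at 30.2 mg/L (12 and 1 when adjusted over the list alone), with hmgcra at 2.17 ± 0.43 and msmo1 at 1.92 ± 0.36. The list shifted by 0.93 (adjusted p = 7.56e-17, and adjusted p = 0.0718 with an estimated correlation), 0.99 with slide as a block, and 0.99 and 0.97 within slides 1 and 2. Of 38 heat shock and chaperone genes, 4 rose and 0 fell (13 and 1 when adjusted over the list alone), with hspb9l at 2.01 ± 0.32 and hsp90aa1.1 at 1.6 ± 0.30. That list shifted by 0.49 (adjusted p = 1.44e-11, and adjusted p = 0.0706 with an estimated correlation), 0.45 with slide as a block, and 0.34 and 0.58 within slides 1 and 2. Of 51 antioxidant and glutathione genes, hmox1a and hmox1b (1.58 ± 0.32) rose and 0 fell (7 and 1 when adjusted over the list alone). This list had a shift of 0.10 (adjusted p = 0.0254, and adjusted p = 0.75 with an estimated correlation), 0.08 with slide as a block, and 0.05 and 0.26 within slides 1 and 2. It lost its call without 30.2 mg/L replicate 3 (adjusted p = 0.205) or control replicate 3 (0.0739) or 4 (0.0635), and with probes above background on all arrays (0.0686). The germ cell score at 30.2 mg/L was -0.14 ± 0.20 (SD, n = 4, exact permutation p = 0.743), and the germ cell and cell cycle lists were not called (adjusted p = 0.863 and 0.601). The aryl hydrocarbon receptor list had 2 of 45 members higher and 0 lower (5 and 2 when adjusted over the list alone) and was not called (adjusted p = 0.115), with a median change of -0.04 and an upward test direction.

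Of 79 cytosolic ribosomal proteins, 0 passed at 30.2 mg/L over all probes and 63 were lower when adjusted over the list alone. The list shifted by -0.60 (adjusted p = 2.44e-28, and adjusted p = 0.59 with an estimated correlation), -0.57 with slide as a block, -0.54 and -0.55 within slides 1 and 2, and -0.04 with quantile normalization (adjusted p = 0.595). Of 73 mitochondrial respiratory chain genes, 0 passed over all probes and 11 were lower when adjusted over the list alone. The list shifted by -0.34 (adjusted p = 8.04e-12, and adjusted p = 0.789 with an estimated correlation), -0.28 with slide as a block, and -0.53 and -0.13 within slides 1 and 2. Of 40 skin and keratin genes, 0 passed over all probes and 10 were lower when adjusted over the list alone. The list shifted by -0.60 (adjusted p = 3.95e-07, and adjusted p = 0.789 with an estimated correlation), -0.53 with slide as a block, and -0.60 and -0.21 within slides 1 and 2. Of 47 proteasome subunits, 0 passed in either count. The list shifted by 0.38 (adjusted p = 3.23e-07, and adjusted p = 0.81 with an estimated correlation), 0.28 with slide as a block, and 1.00 and -0.03 within slides 1 and 2, so the upward shift did not appear within slide 2. Of 24 interferon response genes, 0 passed over all probes and 3 were lower when adjusted over the list alone. The list shifted by -0.52 (adjusted p = 2.7e-05, and adjusted p = 0.698 with an estimated correlation), -0.53 with slide as a block, and -0.34 and -0.67 within slides 1 and 2.

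In 9 further lists called at 30.2 mg/L, 1 gene passed over all probes, pklr of the glycolysis list. Skeletal muscle contractile genes shifted by -0.54, intestine markers by -0.43, leukocyte markers by -0.38, liver secretory markers by -0.36 and glycolysis genes by -0.26. Lens crystallins shifted by -0.24 (0.02 with quantile normalization and 0.01 with cyclic loess), and heart markers, exocrine pancreas enzymes and ionocyte genes shifted by 0.25, 0.18 and 0.15. The 9 had adjusted p from 5.76e-06 to 0.0344, and adjusted p = 0.789 to 0.954 with an estimated correlation. The muscle, glycolysis and lens lists were not called with cyclic loess (adjusted p = 0.225, 0.253 and 0.79) or quantile normalization (0.595, 0.354 and 0.453). Array weights ended the calls of the pancreas, heart, lens and leukocyte lists (0.492, 0.263, 0.135 and 0.0575), and leaving out control replicate 2 and 30.2 mg/L replicate 2 those of the heart, intestine and lens lists (0.178, 0.072 and 0.233). With array weights the shifts were 0.057, 0.34, -0.084 and -0.399, so those of the heart and leukocyte lists did not shrink. Without those 2 arrays they were 0.30, -0.407 and -0.184. The heart list was not called with probes above background on all arrays (0.0745), the intestine, glycolysis, heart and lens lists with normexp (0.0665, 0.11, 0.0907 and 0.561), the pancreas and heart lists with the germ cell score as a covariate (0.0784 and 0.0571), or the pancreas list with slide as a block (0.122). Without 1 array the pancreas list lost its call for 30.2 mg/L replicates 1 (0.213) and 2 (0.0609) and control replicates 1 (0.3) and 4 (0.13). The heart list lost it for 30.2 mg/L replicates 2 (0.0856) and 3 (0.107) and control replicates 1 (0.219) and 2 (0.081), and the lens list for 30.2 mg/L replicate 2 (0.107).

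**Figure D4:**
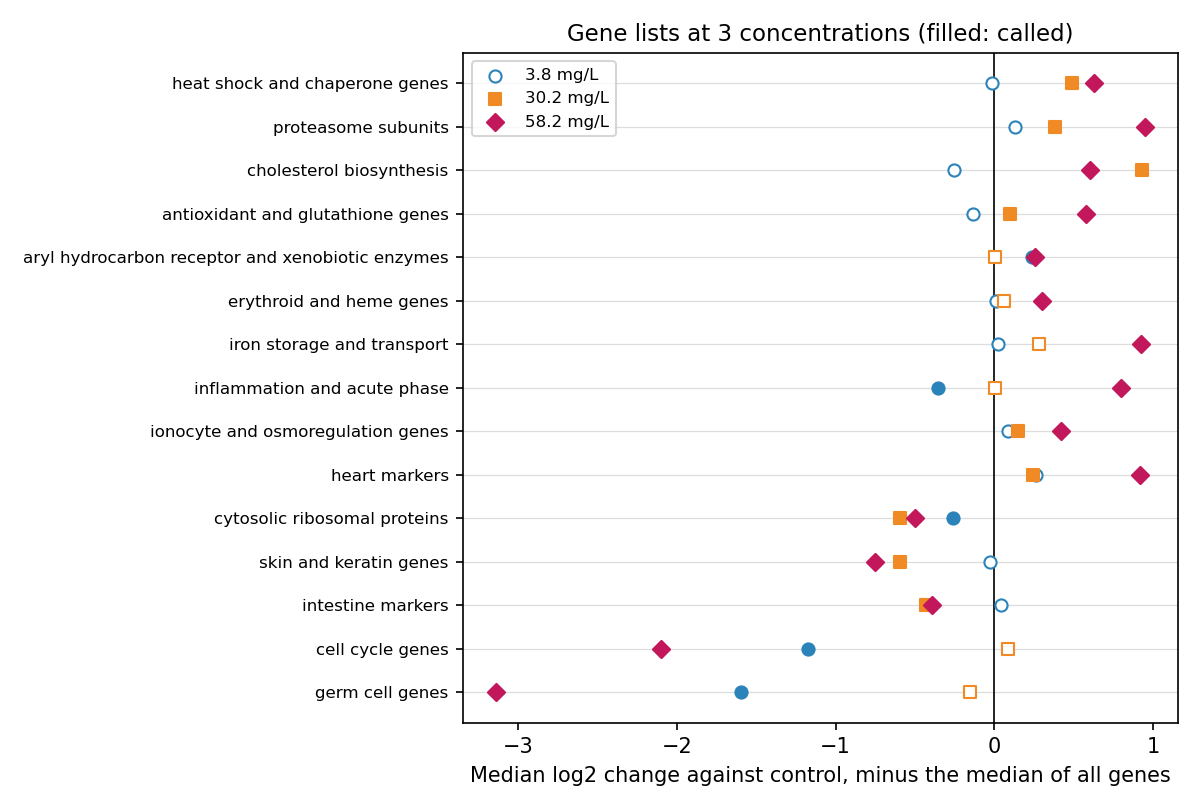
Median log2 change of 15 gene lists against control, minus the median of all genes, at 3.8 mg/L (circles), 30.2 mg/L (squares) and 58.2 mg/L (diamonds). Filled symbols passed camera's test with its preset correlation, none passed with an estimated correlation, and the lowest symbol is the germ cell list at 58.2 mg/L with -3.14. The ribosomal symbols at 3.8 and 30.2 mg/L lay near 0 with quantile normalization, and that at 58.2 mg/L changed sign.

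The probes called at 30.2 mg/L and at 58.2 mg/L overlapped. Of 32119 probes compared, 83 were higher in both and 59 lower in both, where independent lists would share 11.5 and 5.8. Unchanged groups simulated against the same controls shared 0 and 0, but groups without effects have few calls to share, so this is no measure of agreement. No probe (0) had opposite calls. With the controls split into separate pairs the means were 39.3 (20 to 77) and 14.8 (12 to 18). Across probes, which are not independent replicates, the log2 fold changes correlated with r = 0.414, below the 0.519 for unchanged groups simulated with the same controls (-0.209 to 0.885) and 0.198 with split controls. The covariance was 0.21 against 0.091 simulated, a difference of 0.119, and 0.105 with split controls.

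At 3.8 mg/L, 0 of 32311 probes passed in limma, with 2856 at an unadjusted p under 0.05 where 1616 were expected by chance, and the smallest adjusted p was 0.0785. The 10 genes of smallest unadjusted p, none of which passed, included sema6cb, at least 2.13-fold higher (adjusted p = 0.21, log2 0.35 with normexp), cdk10 (-2.07 ± 0.38, adjusted p = 0.22) and lsm6 (-1.18 ± 0.24, adjusted p = 0.33). The groups separated for 1.89% of genes, against 2.86% by chance. The count was 0 with slide as a block and 0 without control replicate 2 and 30.2 mg/L replicate 2, 2 with normexp and 10755 with array weights. Without 3.8 mg/L replicate 1 it was 1, and without 3.8 mg/L replicate 3 it was 876 (167 higher, 709 lower). With control replicate 4 and 3.8 mg/L replicate 3, which share slide 3, in each other's groups it was 9784. The 0 would thus not hold if these 2 labels were exchanged. That split was picked for its count, the highest of 35 splits, so it does not show that an exchange took place. Without the arrays of slide 3, which leaves 1 array at 3.8 mg/L, 619 probes were called and 40.9% of them had the same sign within slide 3, against 39.8% of all probes. The germ cell score at 3.8 mg/L was -1.46 ± 1.475 (SD, n = 4, exact permutation p = 0.2) and ran from -3.08 to 0.28.

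At 3.8 mg/L 11 of 41 lists were called, with 0 members past the threshold over all probes in each and 0 when adjusted over the list alone. The germ cell and cell cycle lists shifted by -1.60 and -1.18 (adjusted p = 4.53e-12 and 1.27e-20, and adjusted p = 0.59 and 0.75 with an estimated correlation). Their shifts were -1.34 and -1.09 with slide as a block, -3.60 and -3.27 within slide 1 and -0.15 and 0.13 within slide 3. With the germ cell score as a covariate the cell cycle list turned to 0.11 and was not called (adjusted p = 0.131). Exocrine pancreas enzymes shifted by 0.50, skeleton, cartilage and collagen genes by 0.36 and aryl hydrocarbon receptor and xenobiotic enzymes by 0.24 (adjusted p = 3.8e-05, 2.7e-05 and 0.00127, and adjusted p = 0.789, 0.789 and 0.794 with an estimated correlation). These 3 had 0.82, 0.18 and 0.32 with slide as a block. Within slides 1 and 3 they had 0.97 and 0.58, 0.33 and -0.12, and 0.39 and 0.12. The xenobiotic list was not called with the germ cell score as a covariate (adjusted p = 0.117). The other 6 lists were ribosomal (-0.26, adjusted p = 3.83e-05), inflammation (-0.35, 0.00988), neuron (0.11, 0.0204), stress axis (-0.21, 0.0257), endoplasmic reticulum (-0.25, 0.0264) and respiratory chain genes (-0.14, 0.0453). With an estimated correlation they had adjusted p from 0.515 to 0.987, and with slide as a block shifts of -0.27, -0.19, 0.15, -0.20, -0.18 and -0.24. In that order they had -0.27, -0.47, 0.49, 0.27, -0.60 and -0.26 within slide 1 and -0.46, -0.24, -0.15, -0.50, -0.06 and -0.49 within slide 3, so the neuron and stress axis lists turned between slides. The neuron and endoplasmic reticulum lists were not called with the germ cell score as a covariate (0.103 and 0.51), and the other 4 and the endoplasmic reticulum list not with array weights (0.192 to 0.949). Each lost the call without 1 of 3.8 mg/L replicates 1, 3 or 4 or control replicates 1, 2 or 4, with adjusted p from 0.0535 to 0.856.

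Between concentrations, 5 of the 12 gene calls of smallest adjusted p named for 30.2 against 3.8 and 58.2 against 30.2 mg/L held with slide as a block. At 30.2 against 3.8 mg/L, hsp70 was higher by 4.47 ± 0.40, hsp70.3 by 3.32 ± 0.29 (adjusted p = 4.1e-05 each), hsp70l by 3.19 ± 0.33 and acat2 by 1.51 ± 0.20. ptgr1.2 was at least 2.34-fold higher and gig2g was lower (log2 -2.71 ± 0.29). Under the slide block hsp70l, gig2g and acat2 lost their calls (adjusted p = 0.052, 0.052 and 0.11). In that contrast 316 probes changed, 97 higher and 219 lower. The majority was higher under the slide block (16 higher, 11 lower, 27 in all) and with the germ cell score as a covariate (71 and 45), and there were 201 without control replicate 2 and 30.2 mg/L replicate 2. Without the arrays of slide 1 only 11 probes were called, and 11 had the same sign within it. At 58.2 against 30.2 mg/L, ptgr1.2 was higher by 3.25 ± 0.40 and lepb, a leptin gene, by 2.62 ± 0.33. opn1mw1, a cone opsin gene (-2.73 ± 0.36), tecrl2b (-2.13 ± 0.29), gata2b (-1.85 ± 0.25) and chmp4c (-1.77 ± 0.23) were lower (adjusted p = 0.0067 for gata2b and 0.006 for each of the other 5). Under the slide block ptgr1.2 and opn1mw1 were called and the other 4 were not (adjusted p = 0.11 to 0.14). With the germ cell score as a covariate opn1mw1 alone was called, and ptgr1.2 and lepb had adjusted p = 0.17 and 0.2. In that contrast 2733 probes changed, 1077 higher and 1656 lower (39.4% higher, against 28.1% with cyclic loess), with 7 under the slide block and 12 with the germ cell score as a covariate. The majority was higher without control replicate 2 and 30.2 mg/L replicate 2 (886 higher and 653 lower, 1539 in all), with array weights (6426 and 3772) and in a fit of only these 2 groups (4328 and 3670). Without the arrays of slides 1 and 2 in turn only 4 and 1 were called, too few to compare signs. The germ cell score differed by -2.80 between these groups (exact permutation p = 0.0286, adjusted p = 0.0858).

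At 58.2 against 3.8 mg/L, hspa1b was higher by 5.55 ± 0.46, hsp70 by 5.46 ± 0.40 and hsp70.3 by 4.32 ± 0.29, and krt1-19e was lower (-7.47 ± 0.59). ptgr1.2 and lepb were at least 22.2-fold and 7.46-fold higher (log2 3.70 and 1.97 with normexp), and the adjusted p of these 6 genes ran from 4.1e-07 to 6.4e-06. In that contrast 2859 probes changed, 1915 higher and 944 lower (67.0% higher, against 56.7% with cyclic loess and 46.8% with the germ cell score as a covariate, 1470 higher to 1670 lower), with 128 under the slide block. Of 1294 called without the arrays of slide 1, 96.3% had the same sign within it, against 68.0% of all probes. Single arrays moved these counts. Without 3.8 mg/L replicate 3 the count for 30.2 against 3.8 mg/L was 6862, and it was 97, 90 and 65 without 3.8 mg/L replicates 1, 2 and 4. It was 98 and 100 without 30.2 mg/L replicates 1 and 4, and without replicate 2 it was 29 higher and 78 lower. Without 30.2 mg/L replicate 3 the higher probes numbered 64. The count for 58.2 against 30.2 mg/L was 58, 117 and 140 without 58.2 mg/L replicates 1, 3 and 4 and 1661, 1374, 1595 and 83 without 30.2 mg/L replicates 1 to 4. Of these, the 117, 140 and 83 were 62, 71 and 44 higher to 55, 69 and 39 lower. The count for 58.2 against 3.8 mg/L was 1504 and 1780 without 58.2 mg/L replicates 1 and 4 and 1674 without 3.8 mg/L replicate 2.

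Along the concentration trend, chaperone genes, hmox1a and cyp1a had the smallest adjusted p. Per doubling of concentration plus 1 mg/L, hsp70 rose by log2 1.01 ± 0.11, hmox1a by 0.92 ± 0.09, hsp70.3 by 0.86 ± 0.07, hsp70l by 0.76 ± 0.08, cyp1a by 0.50 ± 0.055 and matn3a, a cartilage matrix gene, by 0.38 ± 0.045, with adjusted p from 1.1e-05 to 0.00022. In all, 3733 probes had a slope, 2548 upward and 1185 downward (68.3% upward, against 51.0% with normexp). There were 4311 (1924 upward, 2387 downward, 44.6% upward) with the germ cell score as a covariate, 308 (222 upward, 86 downward) with slide as a block and 4328 without control replicate 2 and 30.2 mg/L replicate 2. Without the 58.2 mg/L group 10 probes had a slope, 9 upward and 1 downward, and hsp70, hsp70l and matn3a lost theirs (adjusted p = 0.068, 0.068 and 0.11). Without 58.2 mg/L replicates 1 to 4 there were 2176, 2247, 2437 and 2377.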

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

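The tests of the germ cell and cell cycle pattern, of slides, of the share of red cells and of the whole erythroid list were chosen after the results were seen. Those of the heat shock genes and the 19 called erythroid genes with the germ cell score, of the heat shock genes without 2 arrays, and those on other splits of the arrays, were chosen before their results.

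Germ cell and cell cycle genes were lower at 58.2 mg/L. With the germ cell score as a covariate the mean change of the cell cycle list went from -1.99 (SE 0.57) to 0.34 (SE 0.31, 95% interval -0.35 to 1.03), and within groups the scores correlated with r = 0.944. Less oocyte RNA in the pooled fish may thus account for the fall of the cell cycle genes. The test cannot single out oocyte RNA, since the score followed the first principal component of all genes (45.1% of the variance, r = 0.972). Any other driver of that component would give the same result. Slide is argued against. So are dimmer arrays at 58.2 mg/L, whose 75th percentiles (1550 to 1873) lay above those of the controls (554.4 to 1268). The controls were the dimmer group, so array brightness went along with exposure and cannot be told apart from it. Within slides 1 and 2 the germ cell score differed by -3.48 and -1.9, where the SD of the 4 control scores was 0.67. Each of these differences rests on 1 array at 58.2 mg/L. Genes matched for signal had a median change of 0.00 where the germ cell genes had -3.03. The medians of the sets matched to each germ cell gene ranged from -0.44 to 0.27. Of the 23 genes, 23 were well above background on all 4 controls and 1 is in another list, and the egg coat gene zp3b fell from 16.79 to 13.39 and ca15b from 15.46 to 11.33. Whether the exposure lowered oocyte RNA or the pools held fewer fish with oocytes stays open, since no label gives sex or age.

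hsp70l, hmox1a and cyp1a were higher at 30.2 and 58.2 mg/L. The mean rise within slides 1 and 2 was 2.84 to 4.76. The SD of single arrays within groups was 0.35, so this argues against a difference between slides. Each of these rises rests on 1 or 2 arrays per group. With the germ cell score as a covariate the mean at 58.2 mg/L was 4.24 (SE 0.41) against 4.08 without it, and without the dimmest control and the 30.2 mg/L array of highest negative-control signal the mean at 30.2 mg/L was 3.54 (SE 0.20) against 3.18. All 3 technical explanations that were weighed are thus argued against, and a response of these genes to the exposure is a hypothesis, found and tested on the same arrays.

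Of the 47 erythroid genes, 19 were higher at 58.2 mg/L, with a median rise of 1.80. Tests on these 19 decide nothing, since the genes were picked on the same arrays: hbaa1 and hbba1 against their median gave -1.70 (SE 0.25), the medians within slides 1 and 2 were 1.56 and 1.89, and the median with the germ cell score as a covariate was 1.53. Over the whole list the mean change relative to all genes was 0.88 (95% interval 0.61 to 1.15), 0.84 (0.45 to 1.24) with slide as a factor and 1.00 (0.56 to 1.44) with the germ cell score, which argues against slide and less oocyte RNA as the whole cause of that mean, although the median shifts within slides 1 and 2 were 0.04 and 0.20. A larger share of red cells is argued against by the abundant globin genes hbaa1 and hbba1, whose mean change lay -0.77 (-1.42 to -0.12) from that of the other members, but their own change minus the median of all genes was 0.15 (-0.43 to 0.72) and the list's median shift only 0.30, so a small rise in that share is not excluded. A change in the stage or state of red cells stays open and was not tested.

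For 5 of the 7 counts, no other split of the same arrays gave as many changed probes as the real split. With the real split included, 1 of 35 is the smallest share that 35 splits can give. This argues against chance but does not exclude it. The 7 counts were not adjusted for each other, and the splits ignore slide, which the groups share unevenly. For 30.2 mg/L against control 1 of 35 splits gave as many probes (152, highest other 40), for 58.2 mg/L against control 1 of 35 (7247, highest other 1), for 58.2 against 30.2 mg/L 1 of 35 (2733, highest other 1), for 58.2 against 3.8 mg/L 1 of 35 (2859, highest other 528), and for the trend 1 of 100 drawn splits (3733, highest other 3258). With slide as a block these 5 counts were 38, 1176, 7, 128 and 308, in the order given. For 30.2 against 3.8 mg/L, 2 of 35 gave as many as 316 (highest other 1196), so chance is not argued against there. For 3.8 mg/L against control the real count is 0, so 35 of 35 splits give as many whatever the arrays hold, and the splits say nothing about chance. The split of 3.8 mg/L and control that called 9784 probes set control replicate 4 and 3.8 mg/L replicates 1, 2 and 4, with germ cell scores of -0.94, -2.19, -0.86 and -3.08, against control replicates 1 to 3 and 3.8 mg/L replicate 3, with 0.15 to 0.62. This points to a structure of the samples. It is also the split that an exchange of labels between control replicate 4 and 3.8 mg/L replicate 3, both on slide 3, would give, and then 9784 probes rather than 0 would differ at 3.8 mg/L. The labels were kept as given, and neither an exchange nor the makeup of the pools was tested.

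In 16 of 344 groups of 4 values a single array stood apart from the other 3, where chance would give about 17. Control replicate 4 was the highest for the mean of the mitochondrial respiratory chain (0.45, others -0.20 to -0.10), of the lens crystallins (0.28, others -0.11 to -0.07) and of the leukocyte markers (0.17, others -0.06 to -0.05). 58.2 mg/L replicate 4 stood apart for the mitochondrial respiratory chain (0.03, others -0.11 to -0.10) and 3.8 mg/L replicate 3 for the skin and keratin genes (-0.72, others 0.18 to 0.27) and rho (16.40, others 17.19 to 17.32). Control replicate 2 was the highest for hsp70.3 (9.77, others 8.99 to 9.12) and lgals9l4 (8.69, others 6.89 to 7.17). Among the 3.8 mg/L arrays, replicate 4 stood apart for gclc (12.69, others 12.99 to 13.03) and replicate 2 for sod1 (16.20, others 15.64 to 15.72). Among the 30.2 mg/L arrays, replicate 2 stood apart for srxn1 (7.56, others 7.28 to 7.31) and prdx1 (14.55, others 14.66 to 14.68), and replicate 3 for sod2 (14.83, others 14.15 to 14.18) and gpx1a (15.53, others 14.52 to 14.69). Among the 58.2 mg/L arrays, replicate 3 stood apart for gig2g (9.50, others 8.98 to 9.04) and replicate 1 for hspa5 (16.47, others 15.90 to 15.98).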

How the results depend on the processing

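The settings with a germ cell covariate or without 2 arrays, and the check of the replicate numbers, were chosen after the data were seen. All 7 counts stayed within 1.5 times with quantile normalization, an intensity trend and the authors' values, 0 staying 0. Other counts moved more, in the order 3.8 mg/L, 30.2 mg/L and 58.2 mg/L against control, 30.2 against 3.8, 58.2 against 30.2, 58.2 against 3.8 mg/L and the trend where all are given. Array weights gave 10755, 3520, 16220, 10792, 10198, 8482 and 10362, with weights from 0.177 (3.8 mg/L replicate 3) to 6.344 (control replicate 3). Slide as a fixed block gave 38, 1176, 27, 7, 128 and 308 for the last 6, and as a random block 2443 for 30.2 against 3.8 mg/L. Normexp gave 2 at 3.8 mg/L. For 30.2 mg/L against control and for 30.2 against 3.8 mg/L, cyclic loess gave 324 and 492, no filter on dim probes 68 and 169, and the fit of only the 2 groups 57 and 113, which gave 7998 for 58.2 against 30.2 mg/L. The trend without the 58.2 mg/L group gave 10. The germ cell covariate gave 656, 828, 116 and 12 for 30.2 and 58.2 mg/L against control, 30.2 against 3.8 and 58.2 against 30.2 mg/L, and the fit without 2 arrays gave 201 and 1539 for the last 2. Leaving out 1 array gave 0 to 876, 41 to 278, 4733 to 8348, 65 to 6862, 58 to 2178, 1504 to 2913 and 2176 to 4338, in the order above, and 43 to 51 called list tests against 47. The cause of these moves was not tested, beyond the fewer arrays in some settings. A paired fit with the replicate block gave 75 for 30.2 mg/L against control and 146 for 30.2 against 3.8 mg/L. Of 24 pairs of arrays of the same number 10 correlated above 0.1 (-0.586 to 0.515, mean -0.045), and 4 of 16 arrays were closest to their own number, so the numbers were not taken to pair the arrays.

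Of the 47 called list tests, quantile normalization kept 38, normexp 36, cyclic loess 39, array weights 37, slide as a block 46 and the intensity trend 47, while the estimated correlation kept 0. Quantile normalization reversed the ribosomal list at 3.8 mg/L (test direction, median -0.025) and 58.2 mg/L (0.01), the lens list at 30.2 mg/L (0.019), the respiratory chain at 3.8 mg/L (test direction, -0.026) and the muscle list at 58.2 mg/L (test direction, -0.099). The respiratory chain at 3.8 mg/L also reversed with normexp (-0.015), array weights (-0.084) and without control replicate 4 (-0.086, lowest without any 1 array -0.227), the lens list with cyclic loess (0.014), and the stress axis and inflammation lists at 3.8 mg/L with array weights (0.145 and 0.136). The germ cell covariate reversed the cell cycle list at 3.8 and 58.2 mg/L (0.114 and 0.468) and the neuron list at 3.8 mg/L (-0.099). At 58.2 mg/L it reversed imp3 (0.00), pif1 (0.19), ccnb2 (0.20), ccna2 (0.11), vldlr (0.01), chek2 (0.31) and nanos3 (0.53), the last being part of that score. The cause was not tested. Of the 25 named genes at 30.2 mg/L and 124 at 58.2 mg/L, 25 and 116 kept direction and side of the threshold with quantile normalization, 23 and 118 with normexp, 25 and 120 with cyclic loess and 16 and 119 without a filter on dim probes. Signal over background limits genes such as ptgr1.2, and 5310 probes were never above background.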

Other observations

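At 58.2 mg/L members of several uncalled lists moved in opposite directions. Of 37 leukocyte markers, 8 rose and 9 fell (adjusted p = 0.972). The neutrophil genes mpx (2.61 ± 0.58) and grna.1 (2.26 ± 0.51) rose, and cd8a, a T cell gene (-2.99 ± 0.91), and cd74a, of antigen presentation (-2.65 ± 0.48), fell. Of 43 liver genes, 6 rose and 6 fell (adjusted p = 0.601), with the clotting factor gene f9b at 2.4 ± 0.36 and the secreted protein genes ahsg2 at -2.81 ± 0.51 and fetub at -2.05 ± 0.38. Of 35 p53 and DNA damage genes, 8 rose and 2 fell (adjusted p = 0.608), among them gadd45bb (1.74 ± 0.26), phlda3 (1.33 ± 0.35) and the histone gene h2ax (-2.71 ± 0.43).

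Of 31 gluconeogenesis and fasting response genes, 6 rose and 2 fell at 58.2 mg/L (adjusted p = 0.146). The leptin genes lepb and lepa were at least 7.41-fold and 3.82-fold higher, but had log2 1.3 and 0.65 with normexp, where lepa was not called (adjusted p = 0.092), and gys2, which encodes liver glycogen synthase, fell by 1.33 ± 0.21. Within the muscle list the regulators myod1 (2.56 ± 0.30) and myog (1.82 ± 0.39) and the myosin chaperone gene unc45b (1.82 ± 0.26) rose, while pgam2 fell by 1.22 ± 0.35. In the photoreceptor list 3 of 54 genes rose and 2 fell (adjusted p = 0.379), and rho had -0.20 ± 0.23 (adjusted p = 0.57).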
